A study of Mus musculus with 9 samples.

How the data were processed

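Gene expression was measured on 9 Affymetrix mouse gene arrays, each hybridised with RNA from cells sorted out of the aorta-gonad-mesonephros region of C57Bl6 mouse embryos at embryonic day 11.5. The cells were sorted on CD144 (VE-cadherin, an adhesion protein of endothelial cells, encoded by Cdh5) and CD45 (a phosphatase on the surface of white blood cells and their progenitors, encoded by Ptprc). CD144+CD45- cells are called EC here, CD144+CD45+ cells HSPC and CD144-CD45+ cells HC, with 3 arrays in each of the 3 groups. The sort label of each sample set its group. The labels do not say whether the 3 samples of a group came from separate pools of embryos, so p-values measure only the spread between these samples, which may be technical.

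Per the labels' protocols, total RNA was isolated with a micro-scale column kit, nanogram amounts were amplified to cDNA with the Ovation Pico V2 kit, and the product was labelled with biotin. The protocols name both the Mouse Gene 1.0 ST and the Mouse Gene 2.0 ST array, and do not say which sample went on which. All 9 deposited columns hold the same probe sets. The deposited values are log2 expression values, 1 per probe set and array, and the submitters' processing notes name RMA (background correction, quantile normalization and median polish over the probes of a set) and Partek, with no versions. The array description file and genome build behind the probe sets are not given in the sources used here, and no coordinates are reported. Amplification from little RNA and RMA's shared scale both affect the measurements: differences of weakly expressed genes are compressed towards 0, and a change in the total RNA per cell is not visible. Of the probe sets, 46.6% had an identical value on 2 or more arrays, which median polish can produce. Values carry no detection calls. As a yardstick of background, 1289 olfactory and vomeronasal receptor genes had a median of 3.19 and a 95th percentile of 4.69. Of 316 named differences, 57 had a lower group whose mean was at or under 4.69. Such a difference has only a bound, the mean of the higher group over the mean of, per array, the higher of 4.69 and the lower group's own value, while its adjusted p is that of the fit. The medians of the 9 arrays lay between 5.41 and 5.51. For arrays, the number of samples limits the precision.

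The table held 21115 probe sets, named by Entrez gene number. The platform annotation gave 1 gene symbol to 20405 of them, several to 0 and none to 710, and the unnamed ones were left out of the tests. All 20405 numbers matched a RefSeq gene table of the GRCm38.p6 assembly, used for names alone, with the same symbol. No gene had more than 1 probe set. Related genes of 1 family can share probe sequence, so single members of the Stfa, Ms4a and globin families are uncertain.

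The comparisons were HSPC against EC, HSPC against HC, and HC against EC. Each was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend or robust option), in 1 fit of all 9 arrays with a mean per group. The fit left 6 residual degrees of freedom and eBayes added 2.75. Adjusted p is Benjamini-Hochberg over the 20405 genes of a comparison, with a threshold of 0.05, and differences are on the log2 scale with the standard error (SE) of the fit. An exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.1. Genes past the threshold against both EC and HC in the same direction formed the sets highest and lowest in HSPC. The position of each HSPC array between EC and HC was the median over genes of its distance from the EC mean as a share of the distance between the EC and HC means, with the genes chosen in a fit of the EC and HC arrays alone.

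Before the data were examined, 23 gene lists with 421 entries were written down from general knowledge, of which 394 were measured. A total of 9 genes stand in 2 lists. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 69 tests (23 lists in 3 comparisons). Camera asks whether a list shifts more than the other genes. At the preset correlation 46 of the 69 tests passed the threshold, and with a correlation estimated from the residuals 0 did (camera, with 69 tests); fry, which asks whether a list's genes move one way on balance, called 48. At an unadjusted p under 0.05, 20 tests passed with the estimated correlation. The estimate rests on few residual degrees of freedom. The adjusted p with an estimated correlation is therefore printed beside each list call.

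The rule for naming genes was fixed before the data were examined. It took, per comparison, the 8 largest increases and the 8 largest decreases among genes past the threshold whose arrays did not overlap, the 10 genes standing furthest above both EC and HC in HSPC and the 10 furthest below, the 4 members of each list with the largest differences past the threshold and members past it in the opposite direction, and Cdh5 and Ptprc. Predicted and RIKEN genes, small RNAs, receptor gene segments, chemosensory receptors, histone genes and Y-linked genes were left out. The text gives some of the list members that qualified, up to 4 per list and in some lists 1 or 0, and a member whose call was lost without 1 array is marked or omitted.

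The steps were tested on simulated data before use. In 20 simulations of HSPC against EC over 20405 genes, 200 genes with an EC mean above the median were changed. In addition, 29 cell cycle genes were raised by 1. Of the 200, the fit recovered 40.9% of changes of 0.5, 92.7% of changes of 1 and 99.1% of changes of 2 on the log2 scale. Unchanged genes made up 4.7% of its calls. Noise was drawn independently per gene and array, so these rates do not cover dim genes or correlated noise. The real comparisons called 14.6% to 27.4% of genes, a far larger share than was changed in the simulations. Since the Benjamini-Hochberg cut-off depends on that share, the rates do not carry over directly to the data. Alternatives were a replicate block, a filter on dim probe sets, repeated quantile normalization, median centring, eBayes with trend and robust, array weights, fits of the 2 groups compared, stricter thresholds, other list tests, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.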

Results

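The aorta-gonad-mesonephros region is the part of the mid-gestation embryo where blood stem and progenitor cells emerge from the endothelium of the dorsal aorta. Expression of 20405 named genes was compared between 3 sorted populations of this region in mid-gestation mouse embryos: CD144+CD45- cells (EC), CD144+CD45+ cells (HSPC) and CD144-CD45+ cells (HC). EC carry the endothelial marker alone, HC the blood marker alone, and HSPC both. Each population was measured on 3 arrays, as log2 expression values normalized by the authors.

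The genes encoding the sorted proteins followed the sort. Cdh5, which encodes CD144, stood at 11.70 ± 0.14 in EC, 10.47 ± 0.68 in HSPC and 5.79 ± 0.65 in HC (log2, mean ± SD, n = 3). Its difference between HC and EC was -5.90 (adjusted p = 6.32e-06) and between HSPC and HC 4.68 (adjusted p = 0.000141), while the difference between HSPC and EC was -1.23 with an adjusted p of 0.0574. That last value passed the threshold in some other settings, with an adjusted p of 0.0207 without HSPC replicate 1 and 0.0354 without HC replicate 3. Ptprc, which encodes CD45, stood at 4.42 ± 0.07 in EC, 8.90 ± 0.26 in HSPC and 9.95 ± 0.10 in HC. Ptprc was higher in HSPC than in EC by 4.47 (adjusted p = 3.44e-07) and lower in HSPC than in HC, at -1.06 (adjusted p = 0.000877). Its EC mean lay under 4.69, the 95th percentile of olfactory and vomeronasal receptor genes, which was taken as the background level, so that the difference from EC is a bound of at least 4.21. A single gene's fold given below as "at least" had its lower group's mean at or under that level.

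Along the largest axis of variation, which held 76% of the variance, EC arrays lay between -63.59 and -60.98, HC arrays between 54.42 and 60.18, and the HSPC arrays between them at -13.1, 21.27 and 6.31 for replicates 1, 2 and 3. A second axis, with 11.2% of the variance, set HSPC (-30.99 to -24.67) apart from both EC (11.44 to 12.58) and HC (14.39 to 15.49). Correlation between arrays of 1 population was 0.992 to 0.993 in EC, 0.985 to 0.992 in HSPC and 0.992 to 0.994 in HC. Between HSPC and EC arrays it was 0.945 to 0.971, between HSPC and HC arrays 0.952 to 0.978, and between EC and HC arrays 0.905 to 0.917.

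The comparison of HC with EC sets the fully separated populations against each other. All 19 genes of the pan-leukocyte list were higher in HC, Cd52 by at least 76.3-fold, and all 26 of the endothelial identity list were lower, Emcn by 58.8-fold. The 8 increases with the largest fitted differences were Cd52, a small glycoprotein of white blood cells (at least 76.3-fold), the chemokine Ccl3 (113-fold), the neutrophil calcium-binding protein S100a8 (106-fold), Prg2, the major basic protein of eosinophil granules (at least 91.3-fold), the macrophage lysozyme Lyz2 (99.1-fold), Ms4a6b (at least 69.7-fold), the leukocyte tetraspanin Cd53 (at least 74.8-fold) and Fcrls (at least 71.4-fold). The 8 largest fitted decreases were Klhl4 (at least 48.4-fold lower in HC), Cdh5 itself (59.9-fold), the endothelial sialomucin Emcn (58.8-fold), Tmem255a (53.5-fold), the arterial gap junction gene Gja5 (52.4-fold), S100a16 (49.5-fold), Mmrn2 (at least 35.8-fold) and Adgrf5 (at least 29.6-fold). With background in the lower group, their order is not a ranking. The adjusted p of these 16 genes lay between 6.81e-07 and 6.92e-05. In all, 5586 genes (27.4%) passed the threshold, 3024 higher and 2562 lower in HC, and 2183 of them differed at least 2-fold. The share of calls higher in HC was 54.1%, against 48.6% after repeated quantile normalization, 49% after median centring and 49.7% among calls of at least 2-fold. The arrays of HC and EC did not overlap for 39.2% of all genes, those of HSPC and EC for 28.2% and those of HSPC and HC for 29.6%, where chance gives 10%.

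Every list of vessel genes shifted down in HC. All 26 endothelial identity genes fell (26 adjusted over the list alone), with a median of -4.30 (camera adjusted p = 5.07e-27 and adjusted p = 0.121 with an estimated correlation). Besides Emcn and Mmrn2, the genes included Cldn5, a tight junction protein (-5.42 ± 0.35 SE), and Kdr, the main VEGF receptor (-5.36 ± 0.40 SE). Of 16 arterial genes 15 fell (15 adjusted over the list alone), with a median of -2.26 (adjusted p = 9.76e-12 and adjusted p = 0.149 with an estimated correlation). Members past the threshold included Gja4 (-5.10) and Sox17, an arterial transcription factor (-3.70, a bound of at least 3.34 lower for background in HC). Of 11 venous and lymphatic genes 7 fell (7 adjusted over the list alone), among them Aplnr (-5.01) and Flt4 (-4.79, at least 4.71 lower for the same reason), and 1 rose, the scavenger receptor Stab1 (0.78), which macrophages also express; the list had an adjusted p of 9.95e-05 (adjusted p = 0.111 with an estimated correlation). All 12 basement membrane genes fell (12 adjusted over the list alone), with a median of -3.20 (adjusted p = 4.28e-13 and adjusted p = 0.128 with an estimated correlation). Its called genes included Lama4 (-4.80) and Hspg2 (-4.40).

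In the blood direction, all 19 pan-leukocyte genes rose in HC (19 adjusted over the list alone; median 4.04, adjusted p = 2.43e-19 and adjusted p = 0.111 with an estimated correlation). All 14 granulocyte genes rose as well (14 adjusted over the list alone; median 3.465, adjusted p = 1.87e-13 and adjusted p = 0.0679 with an estimated correlation). The shifted genes included S100a9 at 6.43 and the neutrophil peroxidase Mpo at 6.18. Of 26 macrophage genes 23 rose (23 adjusted over the list alone; median 5.02, adjusted p = 5.65e-17 and adjusted p = 0.149 with an estimated correlation). Called members included the complement gene C1qb at 6.16 and Csf1r, the receptor on which macrophages depend, at 6.08. Lysosome genes (16 of 17 higher, 16 adjusted over the list alone) had an adjusted p of 6.7e-09 (adjusted p = 0.166 with an estimated correlation). Among the called genes were the macrophage protease Ctss at 6.20. Of 23 inflammatory genes 15 rose (18 adjusted over the list alone; adjusted p = 6.27e-09 and adjusted p = 0.149 with an estimated correlation). Genes behind the shift included the chemokine genes Cxcl2 at 5.52 and Ccl4 at 4.31. Mast cell genes rose in 6 of 12 cases (6 adjusted over the list alone; Hdc 3.86 and Cpa3 2.67; adjusted p = 0.00165 and adjusted p = 0.111 with an estimated correlation). Class II antigen presentation genes rose in 4 of 7 cases (4 adjusted over the list alone; Cd74 2.73; adjusted p = 0.00616 and adjusted p = 0.157 with an estimated correlation). EC lay at background for Ctss, Cxcl2, Cpa3 and Cd74, whose differences are bounds of at least 5.85, 5.1, 1.8 and 1.99.

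Signalling and regulatory genes went both ways between HC and EC. In the Notch pathway 12 of 17 genes fell and 3 rose (12 and 3 adjusted over the list alone; median -1.49, adjusted p = 2.32e-06 and adjusted p = 0.111 with an estimated correlation). Members past the threshold included Hey1 at -3.32 and the ligand Dll4 at -3.11 against Notch2 at 2.12 and Rbpj at 0.76. In the BMP and TGF-beta pathway 14 of 21 fell and 2 rose (14 and 3 adjusted over the list alone; adjusted p = 2.32e-06 and adjusted p = 0.121 with an estimated correlation). Its called genes included Eng at -3.60 and Bmp4 at -3.17 against Bmpr1a at 1.38 and Tgfbr1 at 0.91. Blood stem cell transcription factors had 8 of 23 genes higher and 8 lower (11 and 8 adjusted over the list alone; camera adjusted p = 0.859, and 0.00287 with fry). Spi1 (5.13), Runx1 (4.05) and Ikzf1 (3.95) were higher in HC, and Mecom (-3.44), Erg (-3.33), Hoxa9 (-1.64), Mllt3 (-1.21) and Prdm16 (-1.15) were lower. Stem and progenitor surface markers had 9 of 16 higher and 5 lower (10 and 5 adjusted over the list alone; median 0.552, adjusted p = 0.114), with Cd48 at 4.27 and Cd44 at 2.62 against Procr at -3.09 and Cd34 at -1.68. This list passed after repeated quantile normalization (adjusted p = 0.0453) and with fry (0.000392). Mecom lay at background in HC and Cd48 in EC, so that they differed by at least 3.28 and 3.27. Immediate early and heat shock genes, which respond to handling, rose in 7 of 21 cases (7 adjusted over the list alone; adjusted p = 0.0261 and adjusted p = 0.559 with an estimated correlation). The shifted genes included Egr2 at 1.77 and Atf3 at 1.49. This call was lost without EC replicate 3 (adjusted p = 0.172) or HC replicate 1 (0.0516) or 2 (0.0913), with dim probe sets left out (0.0552) and with fry (0.0802). Cell cycle genes were called at an adjusted p of 0.0467 (adjusted p = 0.253 with an estimated correlation). Of 29 such genes 10 were higher and 3 lower (13 and 3 adjusted over the list alone), among them Cdk6 (1.95) and the cell cycle inhibitor Cdkn1c (-2.05). The list's call was lost without EC replicate 1 (adjusted p = 0.0666), HC replicate 2 (0.0934) or HSPC replicate 1 (0.0583) or 2 (0.0619). It was also lost with dim probe sets left out (0.114), repeated quantile normalization (0.0508) and the trend and robust options (0.0511).

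The comparison of HSPC with EC asks what the CD45+ cells of the CD144+ gate express beyond their CD45- neighbours. The 8 increases with the largest fitted differences were in white blood cell genes: Lyz2 (51.9-fold), Mpo (30.4-fold), the signalling adaptor Tyrobp (30.3-fold), Ccl3 (30.0-fold), C1qb (28.4-fold), the leukocyte GTPase Rac2 (27.6-fold), C1qc (27.1-fold) and Cd53 (at least 22.1-fold). The 8 largest fitted decreases were Enpp3 (7.15-fold), Tll1 (at least 5.58-fold), the transcription factor Ebf1 (at least 5.52-fold), the laminin chain Lama4 (6.38-fold), Cd59a (6.17-fold), the fatty acid carrier Fabp4 (6.10-fold), Plpp3 (6.09-fold) and Ehd2 (6.00-fold). The adjusted p of these 16 genes lay between 3.42e-06 and 0.00576. In all, 3366 genes (16.5%) passed the threshold, 1745 higher and 1621 lower in HSPC, 1221 of them at least 2-fold and 2061 at an adjusted p under 0.01. The deposited values gave 51.8% of the calls as higher in HSPC, against 41.5% after centring each array on its median, 48% after repeated quantile normalization and 46.8% among calls of at least 2-fold.

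Transcription factors of blood stem cells rose in 14 of 23 cases and fell in 0 (17 and 1 adjusted over the list alone; median 0.68, camera adjusted p = 4.37e-14 and adjusted p = 0.068 with an estimated correlation). Spi1, a master factor of myeloid cells, was 4.55 ± 0.15 SE above EC, Myb, which definitive blood progenitors require, 4.44 ± 0.12, Hlf 4.40 ± 0.16 and Runx1, which the emergence of blood from endothelium requires, 4.004 ± 0.160. Stem and progenitor surface markers rose in 12 of 16 cases and fell in 2 (12 and 2 adjusted over the list alone; median 1.73, adjusted p = 3.98e-09 and adjusted p = 0.0679 with an estimated correlation). Among the called genes were the adhesion receptor Adgrg1 at 3.83, Cd27 at 3.40 and Cd48 at 3.14, and Cd9 (-0.59) lower. Spi1, Runx1 and Cd48 were also higher in HC than in EC, as given above. For these genes a level above EC is therefore not particular to HSPC. Pan-leukocyte genes rose in 18 of 19 cases (19 adjusted over the list alone; median 3.16, adjusted p = 4.6e-25 and adjusted p = 0.0851 with an estimated correlation). Macrophage genes rose in 23 of 26 (23 adjusted over the list alone; median 3.36, adjusted p = 3.94e-20 and adjusted p = 0.149 with an estimated correlation). Granulocyte genes rose in 5 of 14 (5 adjusted over the list alone; adjusted p = 0.000361 and adjusted p = 0.149 with an estimated correlation). Genes behind the shift included Mpo (4.92), Prtn3 (2.76) and the G-CSF receptor Csf3r (2.54). The inflammatory list (13 of 23 higher, 15 adjusted over the list alone; Cxcl2 4.41 and Tnf 2.34) had an adjusted p of 6.36e-08 (adjusted p = 0.149 with an estimated correlation). The lysosome list, with 10 of 17 higher and 1 lower (10 and 1 adjusted over the list alone; Ctss 4.59, Lgmn 2.60), had an adjusted p of 1.77e-05 (adjusted p = 0.288 with an estimated correlation). EC lay at background for Cd48, Cxcl2 and Ctss, whose differences are bounds of at least 2.14, 4 and 4.25.

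All 4 lists of vessel genes shifted down in HSPC against EC. Of 26 endothelial identity genes 23 fell (26 adjusted over the list alone), with a median of -1.58, which is 3.00-fold (adjusted p = 2.73e-17 and adjusted p = 0.149 with an estimated correlation). Members past the threshold included Kdr (-2.30 ± 0.40 SE), Clec14a (-2.24 ± 0.30) and Cldn5 (-2.17 ± 0.35). Arterial genes fell in 12 of 16 cases (13 adjusted over the list alone; median -1.55, adjusted p = 1.82e-10 and adjusted p = 0.149 with an estimated correlation). Its called genes included the netrin receptor Unc5b at -1.93. Venous and lymphatic genes fell in 8 of 11 (9 adjusted over the list alone; adjusted p = 4.62e-07 and adjusted p = 0.0683 with an estimated correlation). The shifted genes included Flt4 at -2.34, Nrp2 at -2.17 and Nr2f2, a factor of vein identity, at -2.06. Basement membrane genes fell in 10 of 12 (10 adjusted over the list alone; adjusted p = 1.7e-09 and adjusted p = 0.149 with an estimated correlation). Called members included Nid1 at -2.45 and Lamb1 at -2.29. In the Notch pathway 8 of 17 genes fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 5.89e-05 and adjusted p = 0.128 with an estimated correlation). Among the called genes were Dll4 at -1.83, Notch4 at -1.71 and Jag1 at -1.64 against Notch2 at 0.75. In the BMP and TGF-beta pathway 12 of 21 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 1.19e-07 and adjusted p = 0.111 with an estimated correlation). Genes behind the shift included Bmp4 at -2.38, Tgfb2 at -1.96 and Id3, a target of BMP signals, at -1.58. Cell cycle genes rose in 7 of 29 cases and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0057 and adjusted p = 0.149 with an estimated correlation). Members past the threshold included Cdk6 at 1.85 and Ccnd1 at -1.08. With dim probe sets left out the list was not called (adjusted p = 0.0771).

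The comparison of HSPC with HC asks what sets the CD144+ fraction of CD45+ cells apart. The 8 decreases in HSPC with the largest fitted differences, among them granule proteins of neutrophils and eosinophils, were Stfa3 (at least 40.8-fold lower), S100a9 (43.3-fold), S100a8 (42.7-fold), haptoglobin Hp (at least 32.3-fold), Lcn2 (at least 17.1-fold), Prg2 (25.8-fold), Olfm4 (at least 19.4-fold) and the antimicrobial peptide Camp (20-fold). Stfa3 belongs to a family of near-identical genes, so its own share of that signal is uncertain. The 8 largest fitted increases were Cdh5 (25.6-fold), Adgrl4 (17.0-fold), Adgrf5 (at least 10.7-fold), Emcn (16.2-fold), Hlf (15.9-fold), the angiopoietin receptor Tek (at least 13.3-fold), S100a16 (14.5-fold) and Gja5 (13.7-fold). Background in the lower group leaves no ranking among them. The adjusted p of these 16 genes lay between 3.08e-08 and 0.00268. In all, 2983 genes (14.6%) passed the threshold, 1431 higher and 1552 lower in HSPC, 931 of them at least 2-fold and 1482 at an adjusted p under 0.01. The share of calls higher in HSPC was 48%, against 52.7% after repeated quantile normalization and 50.3% with dim probe sets left out. With the EC and HC arrays numbered 3 left out, a setting chosen after seeing their lower globin levels, 1694 genes passed in this comparison.

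All but 1 of the 26 endothelial identity genes were higher in HSPC than in HC (25 adjusted over the list alone; median 2.56, adjusted p = 3.28e-29 and adjusted p = 0.112 with an estimated correlation). Its called genes included Tek at 3.89, Mmrn2 at 3.75 and Myct1 at 3.69. Basement membrane genes rose in 11 of 12 cases (11 adjusted over the list alone; adjusted p = 1.65e-10 and adjusted p = 0.149 with an estimated correlation). The shifted genes included fibronectin Fn1 (2.68). Arterial genes rose in 10 of 16 (11 adjusted over the list alone, with 1 lower; adjusted p = 1.01e-06 and adjusted p = 0.224 with an estimated correlation). Called members included Gja4 at 2.88 and Efnb2 at 2.35. Blood stem cell transcription factors rose in 16 of 23 cases and fell in 1 (18 and 1 adjusted over the list alone; median 0.998, adjusted p = 1.68e-16 and adjusted p = 0.0679 with an estimated correlation). Among the called genes were Hlf at 3.99 ± 0.16 SE, Mecom, a factor of long-term stem cells, at 3.41 ± 0.23, Erg at 3.22 ± 0.14 and Hoxa9 at 1.99 ± 0.14. The gene that fell, Spi1, was at -0.58 with an adjusted p of 0.0365, a call that was lost without EC replicate 2 (adjusted p = 0.0536), HSPC replicate 1 (0.12) or 3 (0.0812), or HC replicate 1 (0.0767), 2 (0.0993) or 3 (0.106). Stem and progenitor surface markers rose in 9 of 16 and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 6.44e-07 and adjusted p = 0.068 with an estimated correlation). Genes behind the shift included Procr at 3.34, Adgrg1 at 2.64, and Kit, the stem cell factor receptor, and Cd27 both at 2.49. Mecom stood at 8.01 in HSPC and 8.04 in EC. Like Mecom, the genes Erg, Hoxa9 and Procr were also lower in HC than in EC. For these 4 genes a level above HC is therefore not particular to HSPC. HC lay at background for Tek, Mmrn2, Myct1 and Mecom, whose differences are bounds of at least 3.73, 3.32, 3.33 and 3.25.

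The granulocyte, macrophage and pan-leukocyte lists shifted down in HSPC against HC, and the megakaryocyte list shifted up. Granulocyte genes fell in 13 of 14 cases (14 adjusted over the list alone; median -2.10, adjusted p = 1.97e-16 and adjusted p = 0.0679 with an estimated correlation). Members past the threshold included Ngp at -4.27. Macrophage genes fell in 19 of 26 and rose in 1 (21 and 2 adjusted over the list alone; median -1.39, adjusted p = 3.24e-08 and adjusted p = 0.293 with an estimated correlation). Its called genes included Cybb at -3.03 and Cd14 at -2.09, against Timd4, a phagocytic receptor of resident macrophages, at 1.60. Pan-leukocyte genes fell in 15 of 19 (17 adjusted over the list alone; median -0.86, adjusted p = 4.35e-09 and adjusted p = 0.157 with an estimated correlation). The shifted genes included Cd52 at -2.42 and Arhgap15 at -2.34. Lysosome genes fell in 13 of 17 (15 adjusted over the list alone; adjusted p = 9.3e-08 and adjusted p = 0.198 with an estimated correlation). Called members included Gas6 at -1.54. Inflammatory genes fell in 10 of 23 cases with 1 higher (13 and 1 adjusted over the list alone; adjusted p = 5.17e-06 and adjusted p = 0.203 with an estimated correlation). Il6 was at -3.20. Mast cell genes fell in 3 of 12 (4 adjusted over the list alone; Hdc -3.51; adjusted p = 0.00169 and adjusted p = 0.111 with an estimated correlation). Class II genes fell in 3 of 7 (5 adjusted over the list alone; Cd74 -2.12; adjusted p = 0.00247 and adjusted p = 0.149 with an estimated correlation). The megakaryocyte and platelet list rose in 5 of 14 with 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.00561 and adjusted p = 0.198 with an estimated correlation). Its called genes included Vwf (3.23), which endothelial cells also make. With dim probe sets left out the list was not called (adjusted p = 0.131). The Notch list rose in 7 of 17 with 2 lower (8 and 3 adjusted over the list alone; adjusted p = 0.00112 and adjusted p = 0.149 with an estimated correlation). Members past the threshold included Mfng at 1.60 and Notch2 at -1.37. The BMP and TGF-beta list had 4 of 21 higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.0426 and adjusted p = 0.352 with an estimated correlation). That call was lost without EC replicate 1 (adjusted p = 0.0519) or 3 (0.0653), HC replicate 3 (0.101) or HSPC replicate 1 (0.123) or 3 (0.0717). It was also lost with dim probe sets left out (0.211), repeated quantile normalization (0.105) and fry (0.0628). HSPC lay at background for Ngp, Il6 and Cd74, which were lower by at least 4, 1.62 and 1.86.

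**Figure D1:**
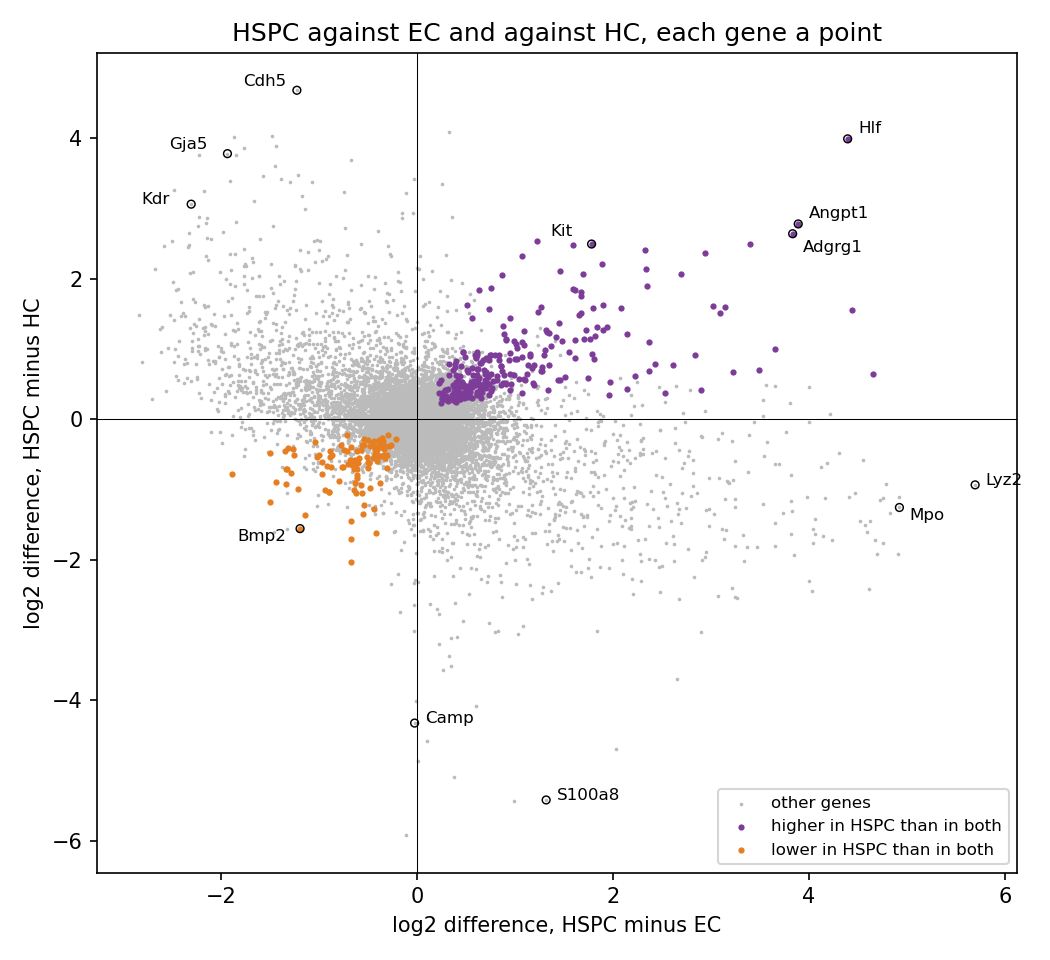
Each point is 1 of 20405 genes, with the log2 difference of HSPC from EC on the horizontal axis and of HSPC from HC on the vertical axis; purple and orange mark the 259 genes higher and the 101 genes lower in HSPC than in both. Hlf lies furthest towards the upper right, at 4.40 and 3.99.

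Genes at their highest in HSPC were led by Hlf, a transcription factor of blood stem cells, at 5.31 ± 0.32 in EC, 9.70 ± 0.10 in HSPC and 5.72 ± 0.17 in HC (log2, SD, n = 3), which is 21.1-fold above EC and 15.9-fold above HC. The others with the largest fitted differences from both were the Tek ligand Angpt1 (14.8-fold and 6.86-fold), Adgrg1 (14.3-fold and 6.23-fold), the costimulatory receptor Cd27 (10.6-fold and 5.61-fold), Rab38 (7.68-fold and 5.14-fold), Hook1 (at least 4.37-fold and 4.39-fold), Stat4 (at least 5.04-fold and 4.19-fold), the carbonic anhydrase Car2 (5.08-fold and 3.73-fold), the keratin Krt18 (3.71-fold and 4.62-fold) and Kit (3.44-fold and 5.62-fold). In all, 259 genes were higher in HSPC than in both EC and HC, 53 of these at least 2-fold from each and 114 at an adjusted p under 0.01. With the EC and HC arrays numbered 3 left out, a setting chosen after seeing their lower globin levels and with fewer arrays, they numbered 148. Independent lists of the same lengths would share 122.4. Simulated arrays with no difference between groups gave at most 0 such genes in 20 data sets, a value that leaves out real effects and does not measure the excess. Because both differences use the same HSPC arrays, part of the excess over that number may come from the shared arrays.

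Genes at their lowest in HSPC differed less. They included Pcdh18 (-1.50 from EC and -1.18 from HC), the annexin Anxa3 (-1.14 and -1.37), the urokinase Plau (-1.22 and -0.99), Gadd45g (-0.938 and -1.001), the transcription factor Prdm1 (-1.34 and -0.92), the RNA-binding protein Zfp36l1 (-0.89 and -1.03) and St6gal1 (-1.44 and -0.89). The call of Bmp2 (-1.19 and -1.56) against EC was lost without EC replicate 1 or 2 or HSPC replicate 1 or 3, with adjusted p of 0.0779, 0.077, 0.0539 and 0.0788. Ctsh (-0.89 and -1.03) lost its call against EC without EC replicate 1 (adjusted p = 0.0831) or HSPC replicate 3 (0.0762), and against HC without HC replicate 2 (0.0641) or 3 (0.058). Ceacam1 (-0.79 and -0.88) lost its call against EC without EC replicate 2 (adjusted p = 0.0559) or 3 (0.0586) or HSPC replicate 2 (0.0527) or 3 (0.0635). The set held 101 genes, 3 of them at least 2-fold from both, fewer than the 123.3 that independent lists would share (at most 0 in the simulated arrays, which leave out real effects). It held 34 at an adjusted p under 0.01, and 55 with the EC and HC arrays numbered 3 left out.

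**Figure D2:**
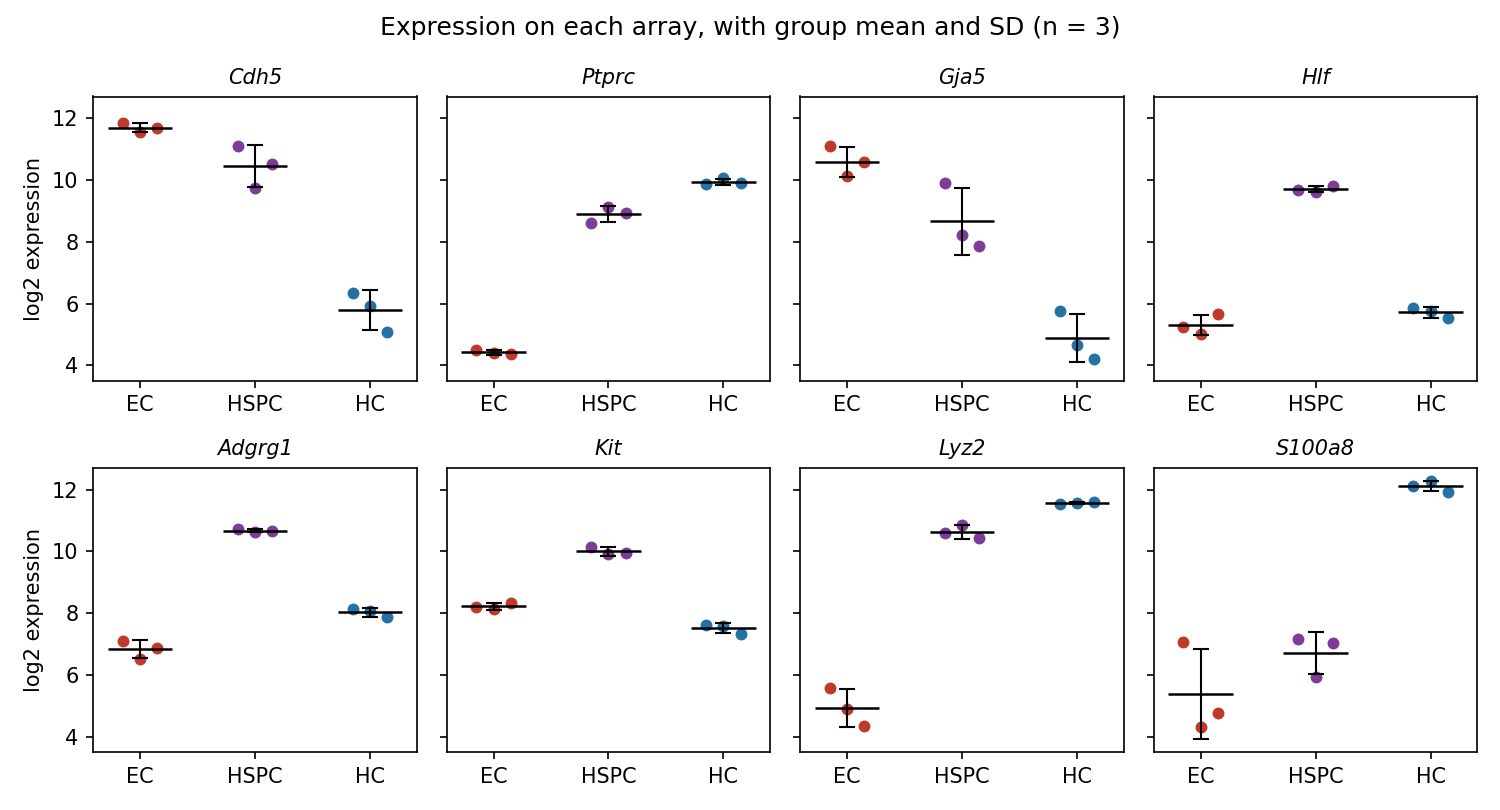
Log2 expression of 8 genes on each array (points), with the mean (line) and SD (bar) of the 3 arrays of a population. Cdh5 and Gja5 are lowest in HC, Ptprc and S100a8 are highest there, and Hlf, Adgrg1 and Kit are highest in HSPC.

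A further 548 genes were above EC and below HC in HSPC, and 470 were below EC and above HC, so that they were past the threshold on both sides in steps. Over 2519 genes higher in EC than in HC, the HSPC arrays lay at 0.417, 0.696 and 0.574 for replicates 1, 2 and 3, where 0 is the EC mean and 1 the HC mean (0.562 ± 0.140, SD, n = 3). Over 2916 genes higher in HC they lay at 0.365, 0.633 and 0.514 (0.504 ± 0.134). No test was made of these positions. The spread between HSPC arrays differed between gene groups. The mean of the endothelial identity list was 8.42 ± 0.60 in HSPC and that of the macrophage list 7.99 ± 0.67, against 8.68 ± 0.10 for the blood stem cell transcription factors and 8.09 ± 0.04 for the stem and progenitor surface markers. Between HC and EC the first 2 lists differed by a mean of -4.20 and 4.25, and the last 2 by 0.328 and 0.677. An array's place between EC and HC therefore moves the first 2 more, so these spreads cannot show that stem cell genes vary less.

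**Figure D3:**
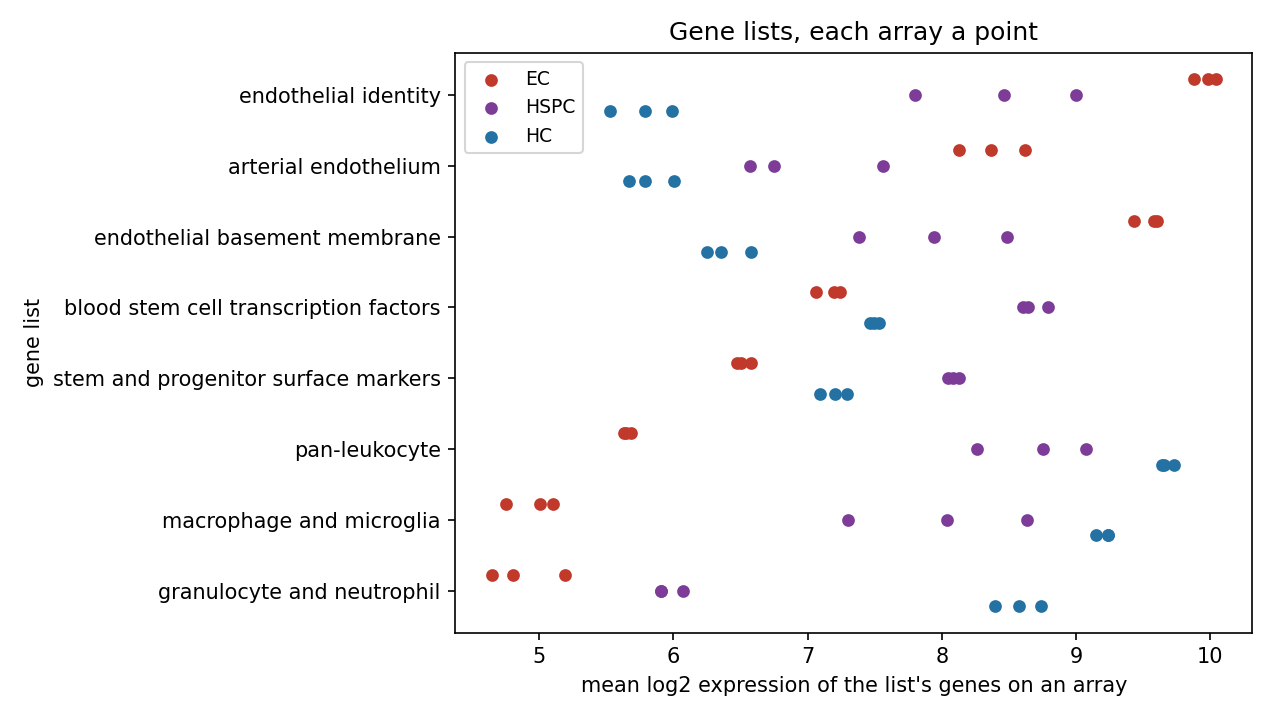
Mean log2 expression over the genes of a list (horizontal axis) for 8 lists (vertical axis), each point 1 array coloured by population. HSPC arrays spread widely between EC and HC for the endothelial and macrophage lists, and lie closely together above EC and HC for both stem cell lists. EC and HC also stand much closer to each other in the stem cell lists.

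Markers of other cell types that the tissue holds were also measured. The mesenchyme and mural cell list was lower in HSPC than in EC (median -0.25, 3 of 18 lower and 3 adjusted over the list alone, adjusted p = 0.00183 and adjusted p = 0.352 with an estimated correlation). It was also lower in HSPC than in HC (median -0.32, 2 of 18 lower and 2 adjusted over the list alone, adjusted p = 0.00523 and adjusted p = 0.393 with an estimated correlation). The second call was lost without HC replicate 1 (adjusted p = 0.0624) and with dim probe sets left out (0.087), and both were lost with fry (0.0693 and 0.0625). The list's mean on arrays 1, 2 and 3 was 5.575, 5.482 and 5.208 in EC, 5.263, 5.088 and 5.254 in HSPC and 5.640, 5.367 and 5.298 in HC. EC array 3 thus lay below HSPC arrays 1 and 3, and the median difference of arrays 1 from arrays 3 over EC and HC was 0.299. Between HC and EC 0 of its 18 genes passed (0 adjusted over the list alone), and the list was not called (adjusted p = 0.773). Lists that were not called are given next with their genes higher and lower in the order HSPC against EC, HSPC against HC, HC against EC. The epithelial and urogenital ridge list had 1 of 14 genes higher and 1 lower, 1 and 0, and 0 and 1 (the same adjusted over the list alone), with adjusted p of 0.314, 0.717 and 0.581, although its member Krt18 was among the genes highest in HSPC. The neural and sympathoadrenal list had 0 of 10 higher and 1 lower, 0 and 0, and 0 and 2 (the same adjusted over the list alone; adjusted p of 0.0871, 0.982 and 0.286, the first 0.0177 without EC replicate 3 and 0.0279 with fry), with the neuronal gene Stmn2 lower in HSPC than in EC (-2.44) and lower in HC than in EC (-3.35). Erythroid genes had 1 of 14 higher and 0 lower, 1 and 2, and 2 and 0 (the same adjusted over the list alone; adjusted p of 0.707, 0.305 and 0.607). Lymphoid genes had 2 of 14 higher and 1 lower, 1 and 3, and 3 and 2 (2 and 1, 1 and 3, and 4 and 2 adjusted over the list alone; adjusted p of 0.717, 0.0597 and 0.155). The second of these passed without HC replicate 2 (0.0283) or 3 (0.0355) or HSPC replicate 2 (0.0448), with array weights (0.0497) and with fry (0.00993), and the third with fry (0.00636).

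Further lists were not called in single comparisons. Venous and lymphatic genes between HSPC and HC had 5 of 11 higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0797). This list passed without HC replicate 1 (0.0387) or HSPC replicate 2 (0.0117), and with a replicate block (0.0428). Between HSPC and EC, mast cell genes had 1 of 12 higher (1 adjusted over the list alone; adjusted p = 0.114, and 0.00979 with fry), class II genes 1 of 7 higher (1 adjusted over the list alone; 0.187) and immediate early genes 1 of 21 higher (1 adjusted over the list alone; 0.102). The immediate early list passed there without EC replicate 1 (0.00249) or HSPC replicate 1 (0.0349) or 2 (0.0429), and also after repeated quantile normalization (0.0425), median centring (0.0305) and array weights (0.0436). Megakaryocyte genes had 3 of 14 higher and 1 lower between HSPC and EC (5 and 1 adjusted over the list alone; 0.1, or 0.0172 without EC replicate 2 and 0.0341 after median centring) and 3 higher and 3 lower between HC and EC (4 and 3 adjusted over the list alone; 0.862). Between HSPC and HC, cell cycle genes had 2 of 29 higher and 1 lower (2 and 1 adjusted over the list alone; 0.982) and immediate early genes 1 of 21 lower (0 adjusted over the list alone; 0.108). The latter passed without HC replicate 3 (0.0209) or HSPC replicate 3 (0.00977). The median, mean and test of a list differed in sign in 9 list comparisons, 0 of them called: erythroid and lymphoid genes for HSPC against EC, epithelial, neural and cell cycle genes for HSPC against HC, and megakaryocyte, mesenchyme, epithelial and neural genes for HC against EC. The mean of 5 globin genes, whose RNA marks red cells, was 11.07, 10.70 and 8.61 on EC arrays 1 to 3, 9.78, 10.11 and 9.91 on the HSPC arrays and 10.44, 10.65 and 9.08 on the HC arrays.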

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

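The settings without the EC and HC arrays numbered 3, with a globin covariate and with all probe sets were chosen after the results were seen, and the others were planned. Direction was followed for 577 called values of named genes and 46 list shifts, of which 0 reversed, and not for the other called genes. All of these were past the threshold on the same arrays, so a reversal was unlikely from the start and its absence says little. The majority direction of the calls did change. Calls of at least 2-fold numbered 1221 for HSPC against EC, 931 for HSPC against HC and 2183 for HC against EC, with 53 genes highest and 3 lowest in HSPC. At an adjusted p under 0.01 there were 2061, 1482 and 3973 calls, with 114 genes highest and 34 lowest. List shifts numbered 46 with the preset correlation, 0 with an estimated one and 48 with fry. Without the EC and HC arrays numbered 3, 1694 genes passed for HSPC against HC, with 148 highest and 55 lowest in HSPC, in a fit of fewer arrays. Leaving out 1 array at a time gave 2672 to 3512, 2140 to 3075 and 4767 to 5697 calls in the 3 comparisons, 177 to 248 genes highest and 68 to 97 lowest, positions of 0.496 to 0.635 and 0.44 to 0.574, and 45 to 48 list shifts. Cdh5 between HSPC and EC passed with the replicate block, the dim filter and the trend and robust options (-1.2257 each), with array weights (-1.2824), without HSPC replicate 1 (-1.5454) and without HC replicate 3 (-1.2257); leaving out arrays gave -0.8712 to -1.5454, and the cause was not tested. The share of calls that were higher was 51.8%, 48% and 54.1% in the 3 comparisons, 48%, 52.7% and 48.6% after repeated quantile normalization, and 41.5%, 43.3% and 49% after median centring. It crossed 50% also at 2-fold for HSPC against EC (46.8%) and HC against EC (49.7%), and with dim probe sets left out for HSPC against HC (50.3%); leaving out 1 array never moved it across. A globin covariate gave 3350, 2851 and 5582 calls with 255 and 98 genes, and all probe sets gave 3477, 3101 and 5796 with 265 and 103. Whether sample numbers pair across groups stayed undecided. Of 9 same-number correlations 1 passed 0.1 (-0.042 to 0.145), that of EC with HC for number 3. Among the 9 arrays 5 correlated best with arrays of their own number. A replicate block gave 3274, 2801 and 5434 calls, 228 and 92 genes, positions of 0.566 and 0.5, and 47 list shifts. Fits of only the 2 groups compared gave 2798, 2335 and 5435 calls, against 3366, 2983 and 5586 in the common fit of all 9 arrays. A mean of all probe sets per gene was not run, because each gene had 1. Signal near background compresses small differences, so genes that did not pass include some that the arrays cannot resolve.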

Other observations

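Of the tests in this part, those of sorted cells in differing numbers and of dilution by EC RNA, of whole HC carry-over, of stromal RNA, of imprinted genes and of ribosome assembly genes were chosen after the results were seen. A first test of EC cells in the HSPC sort (26 of 26 endothelial identity genes with a larger share in HSPC 1 than HSPC 2) was replaced because the pattern itself implies it, and a first test of stromal RNA because it set the level of 1 probe against another.

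Single imprinted genes differed between the populations. H19 and Igf2, neighbours in 1 imprinted cluster, were higher in HSPC than in HC (2.32 and 2.46), and did not pass between HSPC and EC (-0.26 and -0.29, adjusted p = 0.602 and 0.675). Peg10, Grb10 and Igf2r were lower in HC than in EC (-2.99, -2.87 and -3.32). Of 37 measured imprinted genes, 3 were higher and 15 lower in HSPC than in EC (median -0.34), 16 higher and 1 lower in HSPC than in HC (median 0.51), and 3 higher and 21 lower in HC than in EC (median -0.97). By camera at the preset correlation, used for the list calls above, the group had adjusted p of 1.66e-05, 1.39e-07 and 4.16e-09 over 6 tests. With an estimated correlation it passed in 0 of these comparisons (adjusted p = 0.12, 0.0816 and 0.0734 over 6 tests, the last 0.0367 unadjusted). Of the fixed lists, 0 were called with that estimate either.

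Of 65 genes of ribosome assembly, 29 were higher and 0 lower in HSPC than in EC (median 0.32), and 18 were higher and 1 lower in HSPC than in HC (median 0.24). Nop56 (0.67 above EC and 0.48 above HC) and Gnl3 (0.49 and 0.47) were among the 14 that were higher in HSPC than in both. Camera with an estimated correlation gave p = 0.00434 against EC, 0.00515 against HC (each 0.0154 adjusted over 6 tests) and 0.566 for HC against EC. The fixed lists were adjusted over 69 tests, so their adjusted p cannot be compared with these. Granulocyte genes in HSPC against HC, for example, had a camera p of 0.00227 with the estimated correlation, and 0.0679 adjusted. The imprinted and ribosome lists, and the genes named from them, were chosen after their values were seen, so these p-values cannot decide whether either group shifts.

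The HSPC arrays differed in their place between EC and HC. Genes flat between EC and HC spread 1.1 times as much between HSPC arrays as between EC and between HC arrays, which argued against a large loss of array quality. The pairs with HSPC 1 had SDs of 0.213 and 0.214, above the highest between EC or HC arrays (0.195), and HSPC 2 with 3 had 0.188. A smaller loss of quality on HSPC 1 was therefore not excluded. HC cells as a whole in differing numbers would move granulocyte genes along with macrophage genes. In percentage points of the HC level, HSPC 2 lay above HSPC 1 by a median of 1.57 for granulocyte and 39.9 for macrophage genes. This argued against HC cells as a whole, although Mpo (26.8 to 56.1) and Cebpa (8 to 46.6), 2 of 11 granulocyte genes, moved with the macrophage genes. Differing numbers of macrophages alone from the HC population were not tested. EC cells in differing numbers were argued against for the macrophage genes, which were lower on HSPC 1 by a median of 1.61 (quartiles 1.26 and 1.76), where dilution by EC RNA allows at most 0.637. For the endothelial genes they may be a cause, since 90.7% of 54 EC-specific genes were higher on HSPC 1 by 0.5 to 1.5 times the median of 29.8 points. On that array 12 stem cell genes at least 4-fold over EC were lower by a median of 0.127 (quartiles -0.142 and 0.393). This lies within the limit of 0.637, and no lower limit was computed, so the stem cell genes do not decide. EC RNA alone, with the other cells in unchanged proportions, was argued against by the macrophage genes.

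Macrophage genes were above EC in HSPC. Carry-over of HC cells as a whole was argued against, since the median granulocyte gene reached at most 25.4% of the share that the median macrophage gene reached on any HSPC array, although Csf3r reached 57.6% to 73.5% of the HC level. Macrophages inside the double-positive gate might still add RNA, and the test of it was undecided. Macrophage genes differed between HSPC 1 and 2 with a gene-to-gene SD 2.96 times that between HC arrays, under the bound of 3 set for ruling it out. HC arrays hardly differed in the macrophage list (SD 0.052), while HSPC 1 and 2 differed by a median of 1.53 over these genes. The HC spread is thus no fit yardstick, and the ratio cannot decide.

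Genes lowest in HSPC could owe their pattern to stromal RNA in the EC and HC sorts. Their median difference between arrays 1 and 3 of EC and HC was -0.009, against 0.299 for the mesenchyme list. To be called, these genes had to vary little between arrays of 1 population, which keeps that difference small in advance. The mesenchyme list was not chosen in this way, so the test cannot decide on stromal RNA. Splits of 6 arrays number 10, too few to judge: the real split called 3366, 2983 and 5586 genes in HSPC against EC, HSPC against HC and HC against EC, 1 split of 10 in each, and the highest other 0. For lists it called 15, 16 and 15, the highest other 14, 15 and 16, with 1, 1 and 3 splits as large, so camera at its preset correlation calls lists in mixed splits as well. Every mixed split holds unequal numbers of each population on its sides, so part of the real difference remains in it. These calls therefore do not show how often camera calls lists where no difference exists. For the genes highest (259) and lowest (101) in HSPC, 2 of 100 groupings of the 9 arrays gave as many, the real one and 1 with EC whole in the place of HSPC (982 and 846). The other 98 put mixed arrays there and gave at most 0 genes, so the count reflects that the populations differ and does not measure these sets.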
